A study of Mus musculus with 10 samples.

How the data were processed

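RNA from the colons of adult wild-type C57BL/6 mice was sequenced in 10 libraries, 5 from mice given phosphate-buffered saline (PBS) and 5 from mice given 4-HDHA, a hydroxylated derivative of docosahexaenoic acid. Per the labels, all mice drank water with 3% dextran sulfate sodium (DSS) for 7 days, and over the same days received a daily intravenous injection of 200 ul per 20 g body weight of either PBS or 4-HDHA in PBS, its strength written as 5 um. The group and the replicate number of each library were taken from its description in the labels. The labels number the colons and say that mice were divided into groups, but do not state separately that each library is a different animal; if some shared an animal, the p-values would measure only the spread between these libraries.

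Per the labels' protocols, poly(A) RNA was made into strand-marked (dUTP) libraries and sequenced in paired ends on an Illumina instrument. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR, DESeq2 and the mouse genome build mm10; the order of the steps and their settings are not given in the sources used here. The authors deposited whole-number read counts per gene for each library, not normalized, and, in a table with gene names and positions, FPKM values, which are fragments per kilobase of gene model scaled to the size of the library. The counts repeated in that table differed from the count table in 0 cells. The count table holds 55401 genes, of which 32132 had a count in at least 1 library; no line of it stood for anything other than a gene. Of those 32132 gene identifiers, 32042 were found in GENCODE M21 and 29142 (90.95%) had the same chromosome, start and end there, so positions are printed as in the deposited table, on mm10. Several near-identical copies had almost the same count as their partner: the ratio of Gm28437 to mt-Co3 lay between 0.985 and 1.00 and that of Gm28661 to mt-Co2 between 0.944 and 0.976 over the libraries. Reads that fit several places may be counted at each or shared between them, which these ratios cannot tell apart. Values of genes with a near-identical copy are therefore uncertain.

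Counts per library summed to between 50915365 and 66470519, and the totals did not differ between groups (exact permutation p = 0.968, two-sided). Mitochondrial transcripts took a mean of 4.92% of the counts with PBS and 5.74% with 4-HDHA (exact permutation p = 0.0714, two-sided). The most similar pair of libraries, 4-HDHA replicates 1 and 2, had a Spearman correlation of 0.987 across genes. Every library was counted as its own sample on the labels alone; the counts do not show whether any of them share an animal.

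The counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, genes kept by filterByExpr (19615 genes), robust quasi-likelihood F test of the group term, and Benjamini-Hochberg adjustment at 0.05. Fold changes are log2 of 4-HDHA over PBS, with the standard error (SE) implied by the F test. Levels are CPM, counts scaled to library size with the TMM factors. Of 40 gene lists, 38 with at least 5 tested members other than the sex genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with a correlation estimated for each list. For each list, p-values of its members were also adjusted over the list alone. That adjustment made no allowance for the number of lists, and how many members pass it in other splits was not tested. Of the 38 lists, 6 had a member past 0.05 by it. The mean log2 CPM of each list was compared by an exact two-sided permutation over the 252 assignments of the libraries, whose smallest possible p is 0.00794. The separation of the groups was measured as the mean Euclidean distance between groups minus that within groups over the 500 most variable genes, with a one-sided exact permutation test over the same assignments.

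The design, the gene lists, the processing alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 10 genes with the smallest p in each direction among genes with a mean of at least 1 CPM, because none passed the adjusted threshold; up to 4 members with the smallest p of each list described; the sex genes; and Pparg, Ppara, Alox5, Ptgs2, Il1b, Tnf, Il6, Muc2 and Tjp1 whatever their values. The alternatives were DESeq2 1.42.0, limma voom with quality weights, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), where fold changes of low genes are understated, other scalings and filters, covariates for smooth muscle and for lymphoid follicles, the replicate number as a block, and each library left out in turn.

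The procedure was tested on simulated data for this comparison, with counts drawn for the 19615 genes from the means, dispersions and library sizes of the 10 libraries. Among 100 genes changed 2-fold, edgeR recovered 38, and among 100 changed 4-fold it recovered 91, with 6 false calls. DESeq2 recovered 65 and 94, with 60 false calls, and with no gene changed it called 20 genes while edgeR called 0. In a simulation with independent genes, camera recovered 3 of 3 lists raised 1.5-fold and called 0 others. Genes of a list vary together in the real libraries, so this does not show how often camera makes false calls there.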

Results

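Gene expression was measured by RNA sequencing in whole colon tissue of mice with colitis from DSS, a sulfated polysaccharide in the drinking water that injures the colon epithelium. The series has 1 comparison, daily intravenous 4-HDHA against PBS during DSS, with 5 libraries per group and no untreated mice. It asks how 4-HDHA affects gene expression in the inflamed colon. Depth ranged from 50915365 counts (4-HDHA replicate 1) to 66470519 (4-HDHA replicate 5). Ddx3y, a gene of the Y chromosome, was expressed in each library, at 46.4 CPM on average with PBS and 46.3 CPM with 4-HDHA, while Xist, transcribed from the inactive X of females, averaged 4.87 and 11.7 CPM.

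With 4-HDHA, genes of the unfolded protein response in the endoplasmic reticulum were lower and fat cell genes were higher than with PBS by camera with a preset correlation. These calls were lost with an estimated correlation (camera adjusted p = 0.729 and 0.916). Exact permutation of the list means gave an adjusted p of 0.151 for both. Before adjustment both had 0.00794, the smallest possible p, so adjustment over 38 lists left little room to pass. The limma test fry called the unfolded protein response list (directional adjusted p = 0.0251) but not the fat cell list (0.331). Of 25 measured members of the unfolded protein response list, 11 fell and 14 did not pass when p-values were adjusted over the list alone, and of 13 measured fat cell genes 8 rose, 1 fell and 4 did not pass. With 1 library left out, 8 to 11 of the former fell and 4 to 9 of the latter rose, the 4 without 4-HDHA replicate 4. The cell cycle list lay lower in each of its 30 members, by a median log2 fold change of -1.13, and the smooth muscle list lay higher in each of its 22 members, by a median of 0.84. No member of either list passed, over all genes or over the list alone. Both calls were lost with an estimated correlation (camera adjusted p = 0.916 for both), and the exact permutation p of the list means was 0.127 and 0.111 before adjustment. Inflammatory cytokine, neutrophil, junction and mucin lists were not called with all 10 libraries. Each was called lower in some fit with libraries left out, and the cytokine list was called higher with a smooth muscle covariate.

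Over all 19615 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, where the smallest Benjamini-Hochberg adjusted p was 0.283. At an unadjusted p under 0.05 there were 2911 genes, 1449 higher and 1462 lower with 4-HDHA, where 5% of those tested is 981. Genes vary together, so chance can give far more. Other splits of the 10 libraries into 5 and 5 gave a median of 734 and up to 4300. There were 872 higher and 921 lower without PBS replicate 4, 1036 and 857 without 4-HDHA replicate 2, and 942 and 809 without 4-HDHA replicate 4 (1793, 1893 and 1751 in all). The directions were uneven without PBS replicate 1 (1204 and 1874), PBS replicate 3 (1236 and 971), 4-HDHA replicate 3 (1528 and 2202) or 4-HDHA replicate 5 (2138 and 1318). The DESeq2 Wald test called 312 genes, 200 higher and 112 lower, 159 of them at least 2-fold. Of those 312, 308 had been tested by edgeR, each with an unadjusted p of 0.0144 or less there. For 548 genes (2.79%) the CPM values of the groups did not overlap, 228 higher and 320 lower, where chance gives 0.794% on average. How far that share varies over other splits was not tested.

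The 20 genes named next missed the edgeR threshold, each at an adjusted p of 0.283, and all 20 were among the DESeq2 calls. Pdzd2, which encodes a protein with several PDZ domains (chromosome 15, 12359711 to 12739924, minus strand), averaged 6.14 ± 1.03 CPM with PBS and 14.2 ± 1.88 CPM with 4-HDHA (SD, n = 5 each), a log2 fold change of 1.21 (SE 0.16). Cyp26b1, an enzyme that degrades retinoic acid (chromosome 6, 84571414 to 84593908, minus strand), averaged 1.65 ± 0.583 and 5.64 ± 1.89 CPM (SD, n = 5 each), a log2 fold change of 1.77 (SE 0.32). The growth factor receptor Fgfr2 had a log2 fold change of 1.03, the protein kinase C gene Prkcb 1.59, the lubricin gene Prg4 2.19, the receptor subunit gene Kctd12 0.73, the cytoskeletal gene Septin6 0.89, the argonaute gene Ago4 0.76 and 4930523C07Rik 0.86. H2-K2, annotated as a transcribed pseudogene and close in sequence to other class I genes, had 0.82, which is uncertain for that reason. The groups overlapped for Prkcb alone among these 10 genes.

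Tln2, which encodes the adhesion adaptor talin 2 (chromosome 9, 67217087 to 67559703, minus strand), averaged 58.4 ± 15.5 CPM with PBS and 24.6 ± 3.16 CPM with 4-HDHA (SD, n = 5 each), a log2 fold change of -1.24 (SE 0.18). Plek2, a pleckstrin family gene, had a log2 fold change of -1.25 and the matricellular gene Ccn3 -2.42. The chaperone gene Hspa4l had -0.82, the inositol phosphate kinase gene Ippk -0.82, the diacylglycerol lipase gene Daglb -0.70 and the clathrin adaptor gene Ap1s1 -0.49. The other 3 genes, Sdf2l1, Pdia4 and Fkbp11, act in protein folding in the endoplasmic reticulum. In these 10 genes each PBS library lay above each 4-HDHA library.

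**Figure D1:**
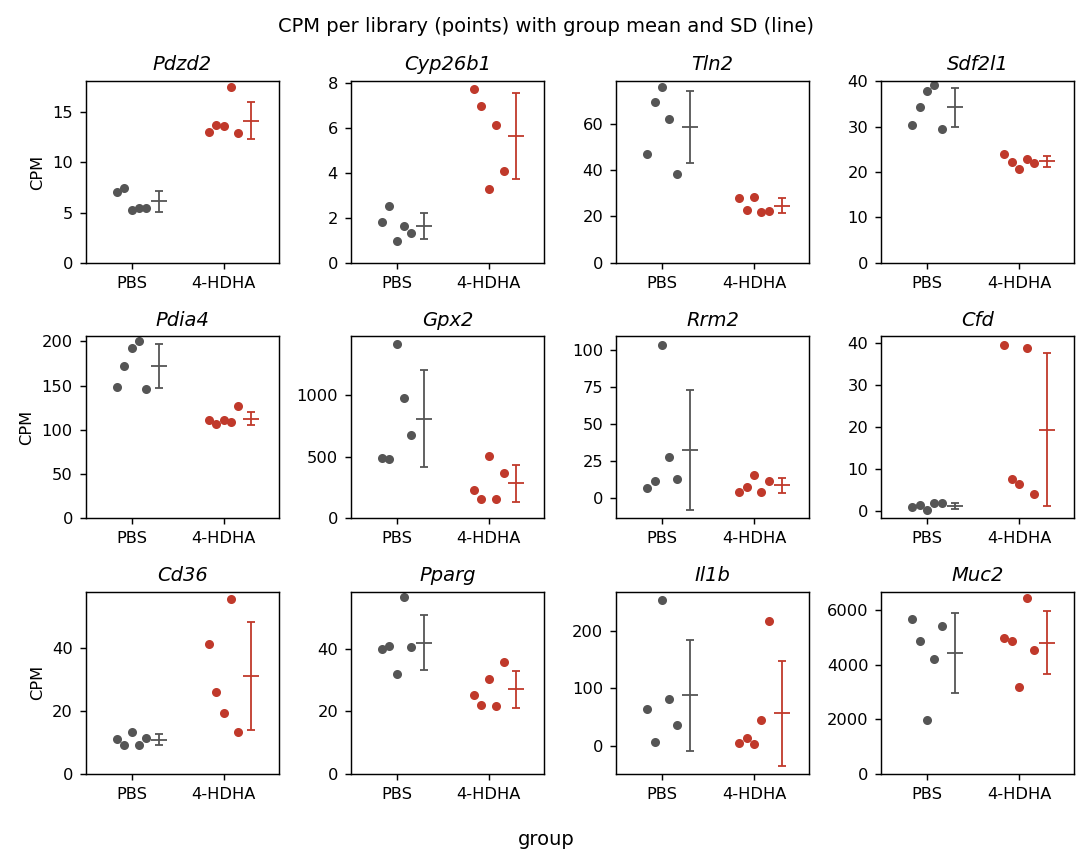
CPM of 12 genes in the PBS and 4-HDHA libraries (x axis: group; y axis: CPM, linear); points are libraries, and the dash and line beside them are the group mean and SD (n = 5). The groups do not overlap for Pdzd2, Cyp26b1, Tln2, Sdf2l1, Pdia4, Cfd and Cd36, and they overlap for Rrm2, Il1b and Muc2.

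The unfolded protein response list was lower with 4-HDHA (camera adjusted p = 1.63e-06, median log2 fold change -0.27; adjusted p = 0.729 with an estimated correlation). It holds genes of protein folding in the endoplasmic reticulum and stress genes such as Ddit3 and Trib3. Of its 25 members 21 had a negative fold change and 4 a positive one, 1 of these at an unadjusted p under 0.05 by edgeR. The mean log2 CPM of the list was lower by 0.29 in an exact permutation test (p = 0.00794, the smallest possible). The groups only just stood apart, with PBS replicate 4 at 6.00219 and 4-HDHA replicate 5 at 5.99995. This list was also the 1 of 38 called by the limma test fry (directional adjusted p = 0.0251). The cochaperone gene Sdf2l1 (chromosome 16, 17130138 to 17132383, minus strand) fell from 34.2 ± 4.34 to 22.4 ± 1.23 CPM (SD, n = 5 each) when adjusted over the list alone (log2 fold change -0.61, adjusted p = 0.00295 by edgeR). The disulfide isomerase genes Pdia4 and Pdia6 had log2 fold changes of -0.61 and -0.49, and the chaperone gene Hsp90b1 of -0.47, all passing over the list alone. DESeq2 called 6 members lower over all genes. In the plasma cell list, which was not called (camera adjusted p = 0.0635) but was lower without PBS replicate 2 (0.0437), PBS replicate 4 (0.0390) or 4-HDHA replicate 5 (0.000381), Fkbp11 was the 1 member of 15 that passed over the list alone, with a log2 fold change of -1.39.

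The cell cycle list was lower (camera adjusted p = 1.23e-08; adjusted p = 0.916 with an estimated correlation), with 0 of 30 members passing over all genes or over the list alone. The ribonucleotide reductase gene Rrm2 had a log2 fold change of -1.93, the cyclin gene Ccne1 -1.40, the thymidylate synthase gene Tyms -1.02 and the replication clamp gene Pcna -0.65. Without PBS replicate 3, Rrm2 had -0.78, Ccne1 -0.54 and Pcna -0.35. The list mean ranged widely within both groups, and its difference of -1.04 gave an exact permutation p of 0.127.

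The NRF2 list, antioxidant genes under the transcription factor NRF2, was lower (camera adjusted p = 0.000125; adjusted p = 0.916 with an estimated correlation). Gpx2, a glutathione peroxidase of the gut epithelium, fell from 807 ± 390 to 283 ± 152 CPM (SD, n = 5 each) when adjusted over the list alone (log2 fold change -1.51, adjusted p = 0.0430 by edgeR). Gclc, the catalytic subunit of glutathione synthesis, had -0.74, and the pentose phosphate genes Tkt and Pgd had -0.83 and -0.46, all passing over the list alone. In all, 6 of 28 members fell by that adjustment and 22 did not pass, but the count was 0 without PBS replicate 1, 3, 4 or 5 or 4-HDHA replicate 1, 2 or 4, and 12 and 11 without PBS replicate 2 and 4-HDHA replicate 3. The oxidative phosphorylation list was lower with a median of -0.19 (camera adjusted p = 9.88e-05; adjusted p = 0.916 with an estimated correlation), 28 of 31 members having a negative fold change and 0 passing over the list alone. Its members with the smallest p were Cyc1 at -0.46 and Uqcrfs1 at -0.39.

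Lists of the outer wall and its connective tissue moved the other way. The smooth muscle list was higher (camera adjusted p = 1.06e-05; adjusted p = 0.916 with an estimated correlation), with 0 of 22 members passing over the list alone. Synpo2 had a log2 fold change of 1.64, Lmod1 1.18 and the myosin kinase gene Mylk 0.82. The mean of this list was lowest within the 4-HDHA group in replicate 5, at 5.30 log2 CPM against 7.12 to 7.55 in the other 4. The endothelial list was higher by a median of 0.45 (camera adjusted p = 9.88e-05; adjusted p = 0.916 with an estimated correlation), with Pecam1 at 0.68 and Tek at 0.77 and 0 members passing over the list alone. The fibroblast list was higher by a median of 0.61 (camera adjusted p = 0.00771; adjusted p = 0.916 with an estimated correlation); Pi16 had 2.24, Thy1 0.88 and Cd34 1.16, and 0 of 20 members passed over the list alone. That call was lost without 4-HDHA replicate 4 (camera adjusted p = 0.118), where Pi16 had 1.44 and Cd34 0.72, or without PBS replicate 4 (0.0577). The enteric neuron and glia list was higher by 0.45 (camera adjusted p = 0.0160; adjusted p = 0.916 with an estimated correlation), with Stmn2, a gene of growing nerve fibers, at 0.75. It was lost without 4-HDHA replicate 4 (camera adjusted p = 0.234), PBS replicate 2 (0.0640) or PBS replicate 4 (0.263). The posterior Hox list, genes of position along the hindgut, was higher by 0.52 (camera adjusted p = 0.0126; adjusted p = 0.916 with an estimated correlation), with Hoxa11 at 0.51 and Hoxd12 at 1.33, and was lost without 4-HDHA replicate 3 (camera adjusted p = 0.0682). No member of either list passed over the list alone. With the smooth muscle mean as a covariate, the fibroblast, neuron and glia, and Hox calls were lost.

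The adipocyte list was higher by a median log2 fold change of 1.47 (camera adjusted p = 9.88e-05; adjusted p = 0.916 with an estimated correlation). Its mean log2 CPM was higher by 1.68, with each 4-HDHA library above each PBS library (exact permutation p = 0.00794, the smallest possible). Cfd, which encodes adipsin, rose from 1.20 ± 0.699 to 19.3 ± 18.2 CPM (SD, n = 5 each) when adjusted over the list alone (log2 fold change 4.01, adjusted p = 0.00709 by edgeR). The adiponectin gene Adipoq had 3.91, the carbonic anhydrase gene Car3 2.83 and the perilipin gene Plin1 3.31, all passing over the list alone, and DESeq2 called 5 members higher over all genes.

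Lists of tissue next to the colon were also higher. The squamous epithelium list had a median of 0.80 (camera adjusted p = 0.0113; adjusted p = 0.916 with an estimated correlation), with Sbsn at 1.14. The skeletal muscle list had 0.84 (camera adjusted p = 0.00381; adjusted p = 0.916 with an estimated correlation), with Pvalb at 2.28. No member of either passed over the list alone. The squamous call was lost without 4-HDHA replicate 5 (camera adjusted p = 0.212), 4-HDHA replicate 4 (0.0758) or PBS replicate 3 (0.111), and the skeletal muscle call without 4-HDHA replicate 5 (0.105). The means of the squamous and skeletal muscle lists were lowest of the 10 libraries in PBS replicate 3, at -2.52 and -2.71 log2 units from the mean of all libraries. They were highest in 4-HDHA replicates 4 and 5, at 1.32 and 1.33 for squamous epithelium and 1.66 and 1.26 for skeletal muscle. Of 15 fixed genes of the exocrine pancreas only 4 were measured, too few for a test, and the erythroid list was not called (camera adjusted p = 0.181), although it was lower without PBS replicate 2 (0.0231) or 4-HDHA replicate 4 (0.00253).

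**Figure D2:**
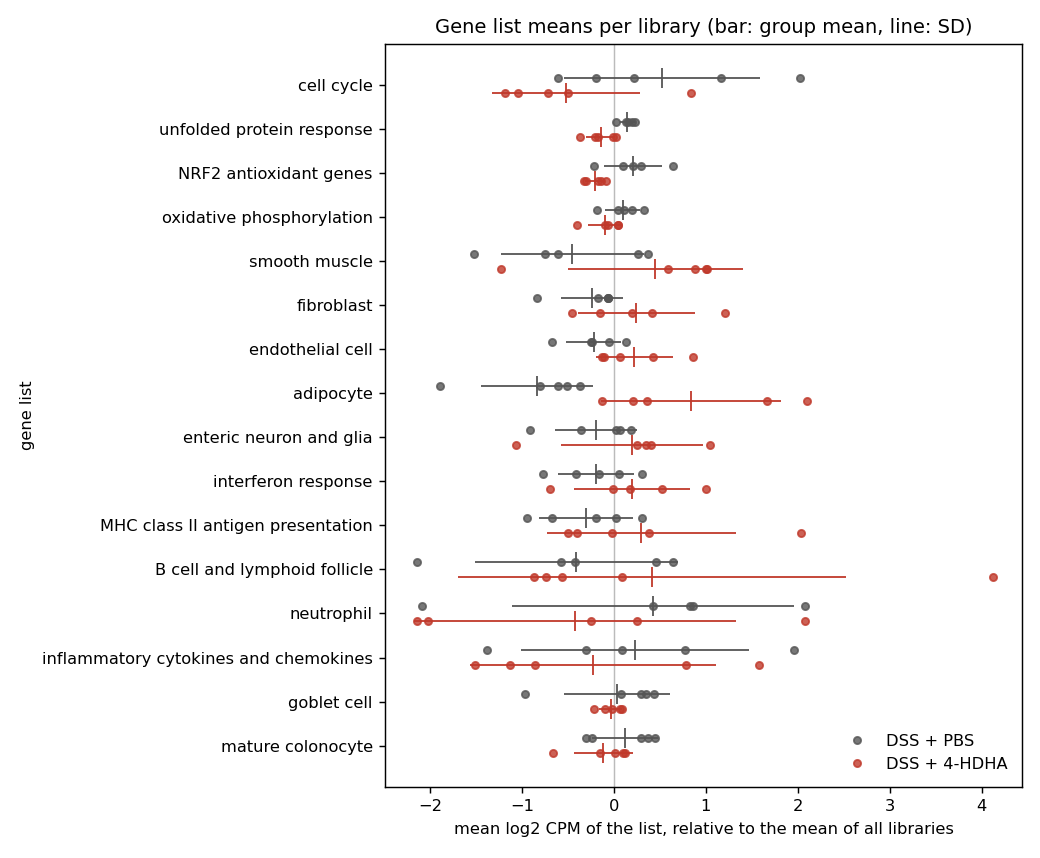
Mean log2 CPM of 16 gene lists in each library, relative to the mean of the 10 libraries (x axis: log2 units; y axis: list); points are libraries, and the bar and line are the group mean and SD (n = 5). The adipocyte and unfolded protein response lists show no overlap between groups. For the latter this is nearly a tie, with PBS replicate 4 at 0.0261 and 4-HDHA replicate 5 at 0.0239. For the B cell and lymphoid follicle list 4-HDHA replicate 5 stands at 4.13.

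Among immune lists, the interferon response list was higher by a median of 0.43 (camera adjusted p = 0.000125; adjusted p = 0.916 with an estimated correlation), with 0 of 40 members passing over the list alone. The guanylate-binding protein gene Gbp2 had 1.04, Ifit3b 1.09 and Ifit3 0.89. Without 4-HDHA replicate 5 the call was lost (camera adjusted p = 0.176). The MHC class II list was higher by 0.65 (camera adjusted p = 0.0147; adjusted p = 0.916 with an estimated correlation), with H2-DMa at 0.65 and 0 of 11 members passing. It was lost without 4-HDHA replicate 5 (camera adjusted p = 0.479) or PBS replicate 2 (0.0825). The B cell and lymphoid follicle list was not called (camera adjusted p = 0.0568): Spib had 2.16 and Pax5 3.09, and without 4-HDHA replicate 5, whose list mean stood 4.13 log2 units above the mean of all libraries, they had 0.53 and -0.30. It was called higher without PBS replicate 3 (camera adjusted p = 0.0173), PBS replicate 5 (0.0284) or 4-HDHA replicate 1 (0.00489), 2 (0.00573), 3 (0.0171) or 4 (0.0437). In the macrophage and monocyte list, not called either (camera adjusted p = 0.0635), Folr2 averaged 5.45 CPM with PBS and 13.4 CPM with 4-HDHA, and Cd68 had a log2 fold change of 0.71; without 4-HDHA replicate 4 their fold changes were 0.85 and 0.47. This list was called higher without PBS replicate 1 (camera adjusted p = 0.0112), PBS replicate 3 (0.0179), 4-HDHA replicate 2 (0.0388) or 4-HDHA replicate 3 (0.00590). The T cell list (camera adjusted p = 0.256, but 0.0262 and higher without 4-HDHA replicate 2) and the mast cell list (0.592) were not called, nor were the inflammasome list (0.741) and the antimicrobial list (0.790).

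The inflammatory cytokine and chemokine list was not called (camera adjusted p = 0.338), with a median log2 fold change of -0.50 and 0 of 26 members passing; the chemokine gene Ccl20 had 1.57, and 0.43 without 4-HDHA replicate 3. The list was called lower without PBS replicate 2 (camera adjusted p = 0.0231) or 4-HDHA replicate 5 (0.0123), and higher with the smooth muscle mean as a covariate (0.00585, in a range of 0.00585 to 0.916 over the alternatives), so its direction is not settled. The neutrophil list was not called either (camera adjusted p = 0.0635); Mmp8 had -1.75 and S100a8 -1.10, with -0.19 and -0.25 without PBS replicate 3 and -3.64 and -2.36 without 4-HDHA replicate 5. It was called lower without PBS replicate 2 (camera adjusted p = 0.000186) or 4-HDHA replicate 2 (0.0447), 4 (0.0172) or 5 (0.000333). The list means of cytokines and neutrophils spanned over 2 log2 units within each group. Il1b averaged 88.0 ± 96.5 CPM with PBS and 56.3 ± 90.9 CPM with 4-HDHA (SD, n = 5 each), a log2 fold change of -0.64 with a 95% interval of -3.16 to 1.87. Il6 had -1.03 (-4.01 to 1.95), Tnf 0.84 (-0.08 to 1.76) and Ptgs2, the inducible cyclooxygenase, -0.78 (-2.89 to 1.33), so that differences of either sign were within the error at this number of libraries. Left out alone, PBS replicate 3 turned the signs of Il1b (0.27), Il6 (1.40) and Ptgs2 (0.18), while without 4-HDHA replicate 5 Il1b had -2.43 and Ptgs2 -1.73, and without 4-HDHA replicate 4 Il6 had -2.24.

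Of the nuclear receptors that bind fatty acids, Pparg had a log2 fold change of -0.63 (95% interval -1.03 to -0.23, adjusted p = 0.293 by edgeR) and Ppara -0.14 (-0.97 to 0.70), with 0.11 without PBS replicate 4 and 0.0013 without 4-HDHA replicate 1. The list of PPAR target genes was not called (camera adjusted p = 0.305, median 0.02). Of its 28 members, 1 passed over the list alone, the fatty acid transporter gene Cd36, which rose from 10.9 ± 1.67 to 31.0 ± 17.2 CPM (SD, n = 5 each), while Cyp4b1 had 0.91. No PPAR target passed over the list alone without PBS replicate 1, 2, 3, 4 or 5 or 4-HDHA replicate 1 or 2. The list of oxylipin synthesis and receptors, which covers enzymes that make hydroxylated fatty acids, was not called (camera adjusted p = 0.276). The prostaglandin receptor gene Ptger3 stood at 0.72, the phospholipase gene Pla2g5 at -0.83 and the lipoxygenase gene Alox5 at 0.48 (-0.15 to 1.12).

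The epithelial lists were not called with all 10 libraries. Goblet cell genes (camera adjusted p = 0.660) included Ang4 at -2.16, and the mucin gene Muc2 stood at 0.12 (95% interval -0.51 to 0.75), with -0.069 without PBS replicate 3 and -0.00053 without 4-HDHA replicate 4. The mucin glycosylation list had a camera adjusted p of 0.660 as well, and was called lower without PBS replicate 3 (0.0252). Epithelial junctions (0.637) included Pkp2 at -0.36 and the tight junction gene Tjp1 at 0.07 (-0.39 to 0.53), with -0.0010 without PBS replicate 2, -0.018 without PBS replicate 3 and -0.023 without 4-HDHA replicate 5. Mature colonocyte genes (0.427) included Tmigd1 at -2.31 and the sodium exchanger gene Slc9a3 at -2.20, and the list was called lower without PBS replicate 3 (camera adjusted p = 0.0362). In the stem and progenitor list (0.999), 2 members rose over the list alone, Tnfrsf19 (log2 fold change 1.81) and the stem cell receptor gene Lgr5 (2.44), which was at 0.291 CPM with PBS and 1.58 CPM with 4-HDHA. That count of 2 was 0 without PBS replicate 1, 3, 4 or 5 or 4-HDHA replicate 4, 1 without PBS replicate 2 or 4-HDHA replicate 1 or 2, and 5 without 4-HDHA replicate 5. Without 4-HDHA replicate 3, 2 rose and 2 fell, and Lgr5 had 1.58. Enteroendocrine genes (0.665) included the peptide hormone gene Insl5 at -0.77, and the wound-associated epithelium list (0.210) included Clu at 2.31, which was 0.74 without 4-HDHA replicate 5. That list was called lower without PBS replicate 4 (camera adjusted p = 0.00657), 4-HDHA replicate 4 (0.0164) or 4-HDHA replicate 5 (0.0418). The xenobiotic list (0.627) had Cyp4f40 at -0.83 and Cyp2e1 at 3.07, and the hypoxia list (0.123) had Ankrd37 at 1.06 and Egln3 at 0.79, and was called higher without PBS replicate 5 (camera adjusted p = 0.00465) or 4-HDHA replicate 3 (0.0230). Tuft cell (0.343), extracellular matrix (0.427) and immediate early genes (0.660) were not called.

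As a whole the groups stood slightly apart: over the 500 most variable genes the mean distance was 65.6 between groups and 61.9 within groups, a difference of 3.75 log2 units (one-sided exact permutation p = 0.0397). That p was over 0.05 without PBS replicate 1 (exact p = 0.111), 3 (0.143) or 4 (0.0794) or 4-HDHA replicate 1 (0.103), 2 (0.0873) or 4 (0.119). The same test also gave a p over 0.05 over all tested genes (0.0635) and on log2(FPKM + 1) (0.103). The first principal component held 26.8% of the variance and separated the groups with an exact permutation p of 0.0476 (two-sided), with PBS replicate 3 at one end (-45.5), 4-HDHA replicate 5 among the PBS libraries (-18.1) and PBS replicate 2 at 9.85.

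In all, camera with the preset correlation called a median of 19 lists in other splits of the 10 libraries into 5 and 5. For the real groups it called 14, 10 higher and 4 lower, and 0 with an estimated correlation. The balance was 8 and 8 without PBS replicate 2, 8 and 7 without 4-HDHA replicate 4, and 6 and 8 without 4-HDHA replicate 5. The exact permutation of list means gave an unadjusted p under 0.05 for 3 lists and 0 after adjustment. With 0.00794 as the smallest possible p, adjustment over 38 lists left little room to pass.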

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

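The search for libraries far from the rest of their group was planned, and no test of a cause was made for the values here. Among 250 groups of 5 values, 1 for each list mean and each named gene per treatment, 28 had a lowest or highest library far from the other 4; chance alone gives about 12, or 1 in 20. Values are log2 CPM.

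4-HDHA replicate 5 accounted for 9 of the 28. Its B cell and lymphoid follicle mean was 5.61 against 0.61 to 1.57 in the other 4 libraries, its T cell mean 2.74 and its Pax5 value 5.79, and 17 of the 18 measured follicle genes had their highest value of the 10 libraries there. Within the 4-HDHA group the same library was lowest for the smooth muscle mean (5.30), Synpo2 (4.74), Lmod1 (4.04) and Fgfr2 (5.74), and highest for Pdia4 (6.98) and Ang4 (0.22). PBS replicate 3 was far below its group for the goblet cell mean (5.78), Muc2 (10.96), the adipocyte mean (-0.28), Adipoq (-4.87), the squamous epithelium mean (-0.31) and Sbsn (0.45).

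PBS replicate 4 was far below its group for the means of wound-associated epithelium (4.29), immediate early genes (4.14) and fibroblasts (5.11) and for Thy1 (2.58) and Gbp2 (7.47), and far above it for Hsp90b1 (10.05). 4-HDHA replicate 4 stood high for the erythroid mean (6.26) and Pdzd2 (4.13) and low for Uqcrfs1 (6.57). 4-HDHA replicate 3 stood low for the mucin glycosylation mean (7.09), the hypoxia mean (6.19) and Pdia6 (7.25), and high for Ccl20 (5.54).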

How the results depend on the processing

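The counts at an unadjusted p, the exact permutation of list means and the fits without both PBS replicate 3 and 4-HDHA replicate 5 were chosen after the data had been seen. The count of 0 genes past the adjusted threshold held at 0.05 in each edgeR and limma alternative, whose smallest adjusted p ranged from 0.0815 (voom) to 0.554. A threshold of 0.10 was counted only in the fit of all 10 libraries without covariates, where it gave 0; voom (0.0815) and the follicle covariate (0.0849) had genes under it. DESeq2 gave 312 genes, 159 at least 2-fold; in the simulation DESeq2 also made more false calls. The 2911 genes at an unadjusted p became 1629 on log2(FPKM + 1), 1622 on log2(FPKM + 0.1), 1346 with the smooth muscle covariate (900 higher, 446 lower), and 1751 to 3730 with 1 library left out, the counts moving by over 1.5 times without PBS replicate 4 (1793), 4-HDHA replicate 2 (1893) or 4-HDHA replicate 4 (1751). Without both PBS replicate 3 and 4-HDHA replicate 5 there were 0 genes past the adjusted threshold, 3181 at an unadjusted p (2116 higher, 1065 lower) and 18 lists (7 higher, 11 lower). Upper quartile scaling gave 1667 higher and 1207 lower. The 14 lists became 0 with an estimated correlation. With fry they became 1 in its directional and 1 in its mixed form. Both times this was the unfolded protein response list (fry adjusted p = 0.0251 and 0.000272). By exact permutation, where the number of assignments limits the p, they became 0. Other alternatives gave 14 to 18, not always the same ones. On log2(FPKM + 1) the B cell, macrophage and hypoxia lists were gained as higher. With the smooth muscle covariate the B cell, T cell, cytokine, macrophage and oxylipin lists were gained as higher, and smooth muscle itself, neurons and glia, fibroblasts and Hox genes were lost. Without both libraries the junction, inflammasome, colonocyte, mucin glycosylation, neutrophil, plasma cell and wound-associated epithelium lists were gained as lower and extracellular matrix as higher, and MHC class II, interferon, skeletal muscle and squamous epithelium were lost. The distance of 3.75 was 8.12 over all tested genes (one-sided exact permutation p = 0.0635) and 2.34 on log2(FPKM + 1) (p = 0.103), and 2.28 to 6.88 with 1 library left out (p from 0.0159 to 0.143). Of 1961 fold changes of 86 genes followed under the alternatives, 1938 kept their direction, 35 genes passed with DESeq2, and 23 values in 8 genes turned. With voom these were Muc2 (-0.0017) and Tjp1 (-0.032); with the smooth muscle covariate Ptgs2 (0.56), Il1b (0.64), Il6 (2.06), Muc2 (-0.065) and Mmp8 (0.036); with the follicle covariate Tjp1 (-0.0071); without both libraries Il6 (1.29), Muc2 (-0.050), Tjp1 (-0.11) and Pax5 (-0.061). With 1 library left out the ranges were -1.73 to 0.18 for Ptgs2, -2.43 to 0.27 for Il1b, -2.24 to 1.40 for Il6, -0.069 to 0.23 for Muc2, -0.023 to 0.21 for Tjp1, -0.34 to 0.11 for Ppara and -0.30 to 3.47 for Pax5. The cause was not tested. Same-numbered libraries of the groups did not deviate together (correlations from -0.316 to 0.0836, 0 of 5 above 0.1, and no library closest to its own number). A weak pairing by number could escape these correlations and is not excluded. With the replicate number as a block, 0 genes passed and 2437 had an unadjusted p under 0.05 (874 higher, 1563 lower). That fit called 15 lists, with B cells and follicles gained as higher. With 5 libraries per group, edgeR recovered 38 of 100 simulated 2-fold changes, so changes of that size can be missed here.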

Other observations

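The tests of Xist with skin genes, muscle genes and H2-Ea were chosen only after the result was seen. So were those of clock genes of the opposite phase, of evening genes without Tef and of the cell cycle list. The same holds for the reading of the own anal margin test, which earlier counted that source as excluded, and of the PPAR target test. Under an earlier reading of the latter (a median of 0.01, bootstrap SE 0.10 over genes, below 0.147) PPAR induction would have counted as excluded. Other splits of the 10 libraries into 5 and 5 do not exclude chance for the numbers of lists, of genes at an unadjusted p and of DESeq2 calls. As many lists as the real 14 were called in 86 of 100 splits, the real one counted among them (median of the others 19, highest 28). At least the real 2911 genes at an unadjusted p under 0.05 were found in 6 of 100, the real one included (highest 4300). DESeq2 called at least the real 312 genes in 4 of 50 splits, the real one included. The others had a median of 11 and a highest of 1418. That highest number is several times the real count, which may come from a structure of the samples. Whether there is one, and its source, was not tested. For the edgeR count of 0 this comparison says nothing, since each of 100 splits has 0 or more (highest 109); the real split has 2911 genes at an unadjusted p and 312 by DESeq2.

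With the smooth muscle mean as a covariate, the median log2 fold change of the cell cycle list was -0.41 in place of -1.13, and the difference of its mean was -0.64 (SE 0.67) in place of -1.04 (SE 0.60). Its camera adjusted p was then 0.000117, in a range of 1.15e-15 to 0.916 over the alternatives, so the part that muscle plays in this difference was not decided. After a trend of fold change on transcript length and GC content was removed, the median was -1.15 (bootstrap SE 0.05 over the 30 genes). That SE does not measure the spread between libraries, and the genes vary together (estimated correlation 0.943).

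Xist, which cells of a male do not express, rose and fell with skin and skeletal muscle genes across the 10 libraries, although Ddx3y lay between 40.8 and 51.1 CPM in all of them. Xist was lowest in PBS replicate 3 (0.512 CPM) and highest in 4-HDHA replicates 4 (24.0 CPM) and 5 (20.4 CPM), and it followed the squamous epithelium mean (Pearson r = 0.983, Spearman rho = 0.818, permutation p = 0.00012 and 0.00541) and the skeletal muscle mean (r = 0.956, rho = 0.903, permutation p = 3e-05 and 0.00076), but not Ddx3y (r = -0.134, rho = -0.152, permutation p = 0.716 and 0.682; all two-sided); over the 7 libraries between the extremes r was 0.702 for the squamous mean (permutation p = 0.0667) and 0.744 for the muscle mean (0.0513). With PBS replicate 3 and 4-HDHA replicate 5 left out r with the squamous mean was 0.942, but this repeats the relation that prompted it and keeps 4-HDHA replicate 4, so skin and muscle of the animal's own anal margin stay open as a source of the skin and muscle genes. H2-Ea, a class II gene that C57BL/6 mice do not express, had 0 counts in PBS replicate 3 and 318 in 4-HDHA replicate 4, but it was chosen after its values were seen, as number 3 of 19614 genes ranked by their correlation with Xist, 76 of them above 0.9, so its r of 0.947 over 8 libraries is no independent evidence. A candidate explanation, RNA or reads of a female animal of another strain at a different dose in each library, therefore stays open, and no biological explanation was tested.

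Evening-phase genes of the circadian clock and its output lay higher with 4-HDHA. Of 12 genes that peak toward evening, 11 were looked up because Tef had been seen and 1 was added once their values were known. All 12 had a positive log2 fold change, among them Tef (0.93), Hlf (1.87), Dbp (1.29), Ciart (1.09) and Per2 (0.53). Of the 12, 8 had an unadjusted p under 0.05 and none passed the edgeR adjustment. Their mean was higher by 0.85 log2 units (SE 0.22), with 5 of 5 4-HDHA libraries above each PBS library, but because Tef prompted the choice, the exact permutation p (0.00794, two-sided) is no independent evidence. With the smooth muscle mean as a covariate the difference was 0.56 (SE 0.15) and with the neutrophil mean, which moved the cytokine list mean from -0.46 to 0.14, it was 0.74 (SE 0.19); without Tef the values were 0.54 (SE 0.15) and 0.73 (SE 0.19). By the rule written before these fits, this counts against a larger share of muscle wall or weaker inflammation as the whole source. It excludes neither, since a list mean is a rough measure of either and the choice of genes may inflate what remains. A part for either stays open. A later hour of collection would lower the genes of the opposite phase (Arntl, Clock, Npas2, Nfil3 and Cry1); their mean was lower by 0.18 with an exact permutation p of 0.246, so collection time stays open and cannot be told apart from an effect of 4-HDHA on the clock.

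Fat cell genes had a mean (though not each gene) that was higher in 5 of 5 4-HDHA libraries than in each PBS library. Among possible sources, fat attached to the outer wall and an action of the compound on PPAR targets were examined. Of 7 markers of the mesothelium, the cell layer over the outer wall and its fat, 5 had a positive log2 fold change, with a median of 0.45 over the 7. The most abundant, Msln, had -1.07 (4.02 CPM with PBS, 1.92 CPM with 4-HDHA) and Upk1b -0.89, while Wt1, near the floor (0.116 and 0.862 CPM), had 2.89. Msln is also a member of the wound-associated epithelium list, so its value need not come from mesothelium. The difference of the mean of the 7 markers was 0.72 with an exact permutation p of 0.286 (two-sided). The 27 PPAR targets outside the fat cell list had a median log2 fold change of 0.01, 15 of them positive, and an exact permutation p of 0.246 (two-sided) for their mean; with members going both ways, a median near 0 decides nothing. Neither test decides, both explanations stay open, and other sources were not tested. Pparg itself had -0.63. The fat cell mean was lowest in PBS replicate 3 (-1.90 log2 units from the mean of all libraries) and highest in 4-HDHA replicate 4 (2.10). These libraries also had the lowest and the highest Xist. However, 4-HDHA replicate 5, high in Xist too, stood at 0.35.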
